A study of Mus musculus with 16 samples.

How the data were processed

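The series holds 16 arrays, 1 per sample, in 8 groups of 2 made by 2 genotypes and 4 conditions. Per the labels' protocols, sorted naive CD4+ T cells were activated for 3 days with antibodies to CD3 and CD28. The stated doses were 10 ug/ml IL-6 and 2.5 ug/ml TGFb, in the unit that the labels give. Total RNA was isolated with a MirVana kit and biotin-labelled with a MessageAmpII kit, per the labels. The authors summarised the probes with RMA, per the submitters' processing notes, and its version and settings are not given in the sources used here. The deposited values were intensity values on a linear scale, 100% of them whole numbers between 6 and 37243. RMA usually ends on a log2 scale, and how the values became linear whole numbers is also not given. Steps between neighbouring values are coarse at the low end. Scanner files and detection calls were not used here. Array medians lay between 66 and 73, and the deposited normalization was kept. The number of arrays limits the precision of every value.

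Groups and replicate numbers came from the sample titles and genotype labels. Of 45101 probe sets, 64 were array controls and were left out. The platform annotation gave exactly 1 gene symbol to 34945 probe sets, several to 932 and no symbol to 9160. Of the 34945, 34741 matched the GRCm38.p6 gene table by Entrez number, all 34741 with the same symbol. No coordinates were used. This named 18193 genes, of which 9010 had several probe sets, and each gene was represented by its probe set with the highest mean over the 16 arrays. Log2 of the deposited intensity was taken with no pseudocount. A gene was tested if it reached log2 6 on at least 2 arrays, which left 13007 genes and set aside 5186. This level minimum stands in for a detection call, and changes of genes whose lower group lies under it depend on the background. Of 76 called values of named genes with further probe sets, 6 had a probe set of opposite sign.

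All 16 arrays were fitted together in limma 3.58.1 (R 4.3.3, with data.table at version 1.17.8) with a mean for each of the 8 groups, so that groups of 2 share 1 estimate of the spread (8 residual degrees of freedom, 3.27 prior degrees of freedom, prior SD 0.267). The 15 comparisons were 4 between genotypes, 8 between conditions within a genotype and 3 interactions. Each used lmFit, contrasts.fit and eBayes with two-sided tests, and Benjamini-Hochberg adjustment over the 13007 genes within the comparison. A gene was called at an adjusted p under 0.05. Beside each test stand the log2 change, its standard error and, where given, the group mean with its SD over 2 arrays. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 16 lists within a comparison, and again with a correlation estimated per list. Members past the threshold were counted over all genes tested and adjusted over the list alone. Of 240 list tests 88 passed with the preset correlation and 4 with an estimated correlation. Between the genotypes 8, 6, 6 and 5 of 16 lists passed under IL-6 with TGFb, IL-6, TGFb and medium. For IL-6 with TGFb, IL-6 and TGFb against medium and IL-6 added to TGFb these were 9, 8, 5 and 7 in WT and 3, 3, 5 and 6 in STAT3-deficient cells, and for the interactions 6, 6 and 5. Outside the genotype comparisons and the interaction with TGFb, only some of these are described, and which was chosen after the results were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

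The groups, tests, gene lists, cell type markers, alternatives and the rule for named genes were fixed before the data were examined, from general knowledge of T cell biology. That plan took the values as log2 or, if linear, to be log-transformed first, and the latter applied. Named were Stat3 with each of its probe sets, and a panel of 20 genes in every comparison of genotypes, of which 16 were measured. Further names were the genes with the largest changes among those past the threshold whose groups did not overlap. These were up to 10 each way for the comparisons of genotypes under IL-6 and IL-6 with TGFb, and up to 5 each way elsewhere and in the interactions, where the condition on overlap was not set. Of each list described, up to 4 members past the threshold with the largest changes were named. A probe set without a single symbol was not named.

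Each group has a replicate 1 and a replicate 2. Over the 28 pairs of groups, deviations from the group mean of same-numbered arrays correlated at 0.11 to 0.86 across genes (median 0.33). The numbers thus pair the samples. The pairing comes from the replicate numbers in the titles, and what the numbers stand for is not stated. All replicate 1 arrays read Xist at 11.91 to 13.21 and Eif2s3y, a gene of the Y chromosome, at 3.81 to 4.52, whereas all replicate 2 arrays read them at 6.64 to 7.6 and at 9.84 to 10.98, so the numbers also part female from male material. The 5' minus 3' difference of the Actb control probe sets was -0.5 to -0.11 on replicate 1 and -1.71 to -0.88 on replicate 2 arrays. Each group holds 1 array of each number, but the Actb difference was not equal across groups. On replicate 2 arrays it was -1.71, -1.22, -1.24 and -1.22 in STAT3-deficient cells (IL-6, IL-6 with TGFb, TGFb, medium) and -1, -0.88, -0.89 and -0.95 in WT cells. The same difference of Gapdh was also lower in STAT3-deficient than WT replicate 2 arrays, at -0.61, -0.39, -0.19 and -0.32 against -0.23, -0.32, -0.17 and -0.21. The fit was repeated with the number as a block (7 residual degrees of freedom). The blocked value stands beside a described result where it changed a call or moved a count by more than 1.5 times.

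The alternatives were the block, the mean of all probe sets of a gene, no level filter, a stricter filter at log2 8, a prior with trend and robust fitting, a further quantile normalization, array weights, only the 4 arrays compared, and leaving out each array. In the last, a group of 1 array is assumed to vary like the others, and the replicate numbers are no longer balanced. Added after seeing the data were fits without both replicate 1 arrays of TGFb or of medium, a fit with the STAT3-deficient TGFb and IL-6 with TGFb replicate 1 arrays exchanged, a fit with both the block and the Actb 5' minus 3' difference as a covariate, list tests with both the block and an estimated correlation, list tests after a further quantile normalization, and counts for probe sets without a single symbol. The code was tested on simulated data of 13007 genes, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. Between the genotypes under IL-6 with TGFb, 1.49%, 10.4% and 72.7% of these were recovered, with 6 false calls. Under IL-6 these were 0%, 16.4% and 83.3%, with 2 false calls, so changes near 2-fold are mostly missed with 2 arrays per group. In simulated arrays, a list of 25 genes shifted by -0.7 was found (adjusted p = 9.94e-25), and 0 of 20 unshifted lists passed camera's test.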

Results

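Gene expression was measured on 16 Affymetrix arrays of mouse CD4+ T cells, 8 from STAT3-deficient cells and 8 from wild-type (WT) cells. STAT3 is the transcription factor that the IL-6 receptor activates. Per the labels, the deficient cells carried floxed Stat3 alleles and a Cre recombinase under CD4 control, and the WT cells carried the floxed alleles alone. Naive cells (CD44-, CD62L+) were sorted and activated for 3 days through CD3 and CD28. They were kept in medium, in IL-6, in TGFb or in IL-6 with TGFb, the combination under which naive cells become IL-17-producing Th17 cells. Each of the 8 groups held 2 arrays, which limits the precision of every value. Median intensity per array lay between 66 and 73, and the 75th percentile between log2 7.7 and 8.09. Where the replicates came from is not stated, so p-values measure only the spread between these samples, whose replicate numbers 1 and 2 differed in sex-linked genes.

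Stat3 itself was read first, to check the labels. Under IL-6, its brightest probe set (1460700_at) read log2 8.65 ± 0.11 in STAT3-deficient and 11.76 ± 0.48 in WT cells (SD, n = 2). This was a fall of 8.59-fold (log2 change -3.1, SE 0.58, adjusted p = 0.0224). Under IL-6 with TGFb the levels were 9.28 ± 0.39 and 12 ± 0.26, a log2 change of -2.72. That change lay at the threshold (adjusted p = 0.05002) and passed it with the replicate number as a block (adjusted p = 0.0052). Under TGFb the levels were 9.46 ± 1.42 and 11.98 ± 0.28, and in medium 8.77 ± 0.52 and 10.82 ± 0.85. These changes of -2.52 and -2.05 had unadjusted p = 0.0011 and 0.0044 in limma's test and did not pass the adjustment over all genes (adjusted p = 1). Of the 8 WT arrays, 7 lay above every STAT3-deficient array, and WT medium replicate 1 (10.22) lay below STAT3-deficient TGFb replicate 2 (10.46). A second probe set, 1426587_a_at, changed by -2.67 and -3.57 under IL-6 with TGFb and under IL-6 (adjusted p = 0.0172 and 0.00622), and by -2.44 and -2.06 under TGFb and in medium. The dimmer probe sets 1424272_at and 1459961_a_at gave changes between -1.24 and -0.17. The position of these probe sets relative to the deleted part of the gene was not known here, so the lower values show that the labels and the arrays go together, and a probe set outside that part would check nothing. The call under IL-6 was lost without STAT3-deficient IL-6 replicate 1 (change -3.18), without its replicate 2 (-3.02) and without WT IL-6 replicate 2 (-2.76). The change under TGFb passed the threshold without STAT3-deficient TGFb replicate 2 (-3.53).

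**Figure D1:**
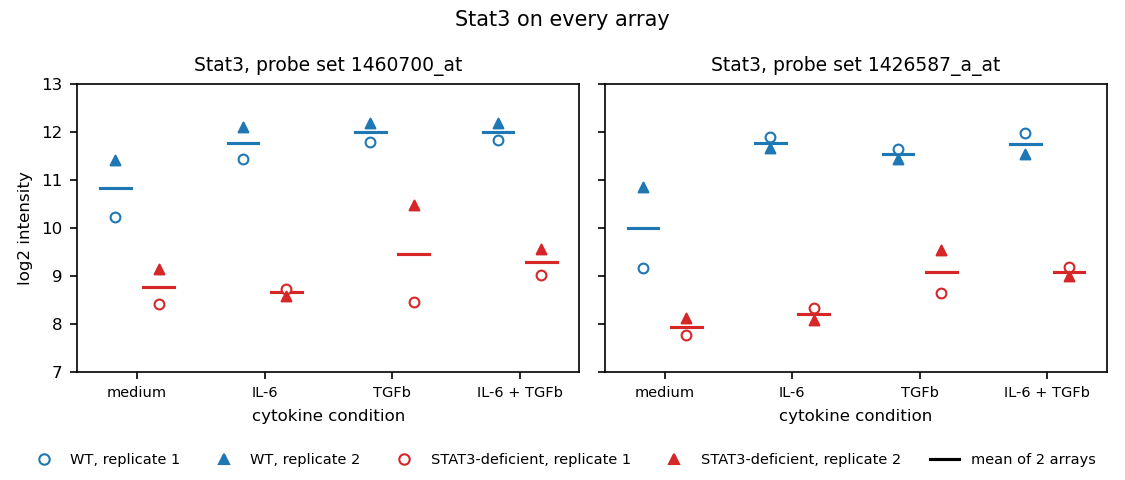
Log2 intensity of Stat3 (y axis) on each of the 16 arrays (points) for probe sets 1460700_at and 1426587_a_at, by genotype and condition (x axis), with bars at the mean of 2 arrays. STAT3-deficient arrays lie below WT arrays of the same condition, and the highest STAT3-deficient value of 1460700_at is 10.46.

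The cultures carried the profile of T cells. The median level of 10 measured T cell markers was log2 11.2 over the arrays. Markers of CD8 T cells, gamma delta T cells, mast cells and basophils, and erythroid cells stayed under log2 8 on all 16 arrays, with highest values of 7.43, 7.56, 7.89 and 6.04. Of 8 NK cell markers 7 stayed under log2 8, and the exception, Klrd1, reached 12.85 in WT cells under IL-6 with TGFb. Of 10 B cell markers 9 stayed under it, and Ighm read 9.49 to 11.94 on all arrays. The same held for 15 of 16 myeloid markers (Mpeg1 reached 8.15) and 3 of 4 platelet markers (Itga2b reached 8.37). It held for 5 of 9 dendritic cell markers, with H2-Ab1 the highest of the others (11.32), and for 5 of 7 stromal markers, with Epcam (10.18) and Pecam1 (9.16) above it.

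The first question was what STAT3 contributes under the Th17 condition. With IL-6 and TGFb present, STAT3-deficient cells showed far less Il21 and Il17a than WT cells. Il21, a cytokine of Th17 and follicular helper T cells, was 154-fold lower (log2 change -7.26, SE 0.53, n = 2 arrays per group, adjusted p = 0.00027). It read 11.96 ± 0.6 in WT cells and lay below the level minimum of log2 6 in STAT3-deficient cells, so the size of the fall depends on the background. Il17a, the defining Th17 cytokine, fell from 10.87 ± 1.01 to 6.4 ± 0.16, which is 22.2-fold (adjusted p = 0.0234). Rora, a nuclear receptor of Th17 differentiation, fell by 3.04 on the log2 scale (adjusted p = 0.00268), although 1 of its 7 other probe sets had the opposite sign. Tmem176b, a membrane protein of the same list, fell by 2.61 (SE 0.31, adjusted p = 0.00221).

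Further genes were far lower. Serpinb1a, a protease inhibitor, Timp1, an inhibitor of metalloproteinases, and Selp, the adhesion molecule P-selectin, had log2 changes of -6.77, -5.88 and -5.12 (adjusted p = 0.00818, 0.00691 and 0.00492). Gatm, an enzyme of creatine synthesis, and Plac8 changed by -4.97 and -4.88 (adjusted p = 0.0262 and 0.0174). Cysltr1, a leukotriene receptor, Gm17767 and Pdpn, the glycoprotein podoplanin, changed by -4.67, -4.42 and -4.29 (adjusted p = 0.0419, 0.00097 and 0.00221). Gpr15, a receptor that guides T cells to the colon, fell by 3.39 (SE 0.29, adjusted p = 0.00089). Of these, Serpinb1a, Timp1, Gatm, Cysltr1, Gm17767 and Pdpn lay below log2 6 without STAT3.

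Fewer genes were higher without STAT3. Nkg7, a protein of cytotoxic granules, rose from 6.73 ± 0.29 to 12.28 ± 0.81 (SD, n = 2), or 46.9-fold (adjusted p = 0.0165). The chemokine Ccl1 rose by 5.36, carbonic anhydrase Car2 by 4.71 and Lad1 by 4.59 (adjusted p = 0.0147, 0.0131 and 0.006). Ikzf2, which encodes Helios, a transcription factor of regulatory T cells, rose from 7.31 ± 0.12 to 11.54 ± 0.53 (SD, n = 2), or 18.7-fold (adjusted p = 0.00818). Tnfsf11, which encodes RANKL, rose 11.3-fold (log2 change 3.49, SE 0.38, adjusted p = 0.00168). Penk, Drc1, 2900026A02Rik and Scin rose by 3.45, 2.93, 2.77 and 2.31 (adjusted p = 0.0421, 0.0425, 0.00867 and 0.0234). Lad1 and Scin lay below log2 6 in WT cells.

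Of the 20 genes of a panel chosen beforehand, 16 were measured and 3 passed the test, namely Il21, Il17a and Rora. Socs3, the feedback inhibitor of cytokine signalling, read 8.92 ± 0.41 and 12.56 ± 0.08 (SD, n = 2), a change of -3.64 that did not pass (adjusted p = 0.184) and passed with the block (adjusted p = 0.0269). The same held for Bcl3, a cofactor of NF-kB, at -2.24 (adjusted p = 0.271, and 0.00495 with the block). The transcription factors Batf, Maf and Ahr differed by -1.88, -1.81 and -2.45, and Il10 by -4.04 (adjusted p = 0.118, 0.128, 0.116 and 0.0783). For Ifng and Tbx21, the cytokine and transcription factor of Th1 cells, the changes were 4.99 and 2.24 (adjusted p = 0.326 and 0.705). Foxp3, the transcription factor of regulatory T cells, read 8.17 ± 1.16 and 6.35 ± 2.19 (SD, n = 2, adjusted p = 0.759). The values for Gata3, Bcl6, Bcl2 and Il6ra were 1.35, -0.55, 0.18 and -0.71, with adjusted p from 0.746 to 0.966.

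Among 23 measured genes of the Th17 list, 5 fell and 0 rose over all genes tested, and 12 fell and 0 rose adjusted over the list alone. Its median log2 change was -1.56 (adjusted p = 5.1e-13, and adjusted p = 0.011 with an estimated correlation). With both the block and an estimated correlation this call was lost (adjusted p = 0.062). Among 28 STAT3 targets and IL-6 feedback genes, 3 fell, and 9 fell adjusted over the list alone, with a median of -0.99 (adjusted p = 1.5e-07, and adjusted p = 0.21 with an estimated correlation). With the block, 7 of its members fell. The members that passed were Sbno2, Jak3, the kinase of the common gamma chain receptors, and Icos, a costimulatory receptor, which changed by -1.84, -1.2 and -0.97. Of 17 follicular helper genes 2 fell (Il21 and Icos), and 4 fell adjusted over the list alone. Their median was -0.55 (adjusted p = 0.01, and adjusted p = 0.41 with an estimated correlation).

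The other lists moved less or in both directions. Of 30 genes of TGFb response and regulatory T cells, 1 rose (Ikzf2) and 1 fell (Gpr15), against 2 and 1 adjusted over the list alone and 1 and 2 with the block. The median of 0.04 and mean of 0.18 were above 0 while the test leaned down (adjusted p = 0.88). The 19 Th1 genes had a median of 1.15 (adjusted p = 0.0056, and adjusted p = 0.21 with an estimated correlation), with 0 calls over all genes, and 4 higher and 1 lower adjusted over the list alone and equally with the block. The Th2 list of 15 genes had a median of -0.33 (adjusted p = 0.34), with Ccl1 higher and Ecm1, an extracellular matrix protein, lower (log2 change -2.89), against 1 higher and 4 lower adjusted over the list alone and 1 higher and 2 lower with the block. Of 13 cytotoxic effectors 2 rose, Nkg7 and Gzmk, a granzyme (log2 change 1.64), against 3 higher and 1 lower adjusted over the list alone and equally with the block, with a median of 0.06 (adjusted p = 0.077). The aryl hydrocarbon receptor list of 7 genes held 1 higher call (Scin), and 1 higher and 4 lower adjusted over the list alone. Its median was -0.6 (adjusted p = 0.054, with adjusted p = 0.045 with the block and adjusted p = 0.029 after a further quantile normalization). Without WT replicate 2 the Th1 call was lost (adjusted p = 0.075), while the cytotoxic list passed without replicate 1 of either genotype and the aryl hydrocarbon receptor list without WT replicate 1 (lowest adjusted p = 0.015 and 0.018).

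A further set of lists held 0 members past limma's test over all genes. The 42 interferon response genes had a median of 0.47 (adjusted p = 0.0056, and adjusted p = 0.65 with an estimated correlation), and the 48 cell cycle genes 0.33 (adjusted p = 0.00022, and adjusted p = 0.55 with an estimated correlation). The 31 glycolysis and hypoxia genes had a median of -0.48 (adjusted p = 0.01, and adjusted p = 0.67 with an estimated correlation). The 23 genes of naive cells and migration had a median of -0.31 (adjusted p = 0.036, and adjusted p = 0.21 with an estimated correlation), and 2 of them fell with the block. Adjusted over the list alone, 0 members passed in these 4 lists. The 28 survival genes (median -0.24), 33 early activation genes (0.23), 21 sterol genes (0.25) and 4 sex-linked genes (-0.3) gave adjusted p = 0.23, 0.091, 0.068 and 0.99. Adjusted over the list alone, 1 survival gene was higher, 1 early activation gene was higher and 2 were lower. With the block, 1 interferon response gene and 1 survival gene were higher, and 1 early activation gene was higher and 1 lower. The interferon call was lost without WT replicate 2 (adjusted p = 0.29) and the call of naive and migration genes without STAT3-deficient replicate 1 or WT replicate 2 (up to 0.083). The early activation list passed without STAT3-deficient replicate 1 (0.0044), and the sterol list without STAT3-deficient replicate 2 or WT replicate 1 (as low as 0.0021).

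In all, 27 of 13007 genes were higher and 128 lower without STAT3 under IL-6 with TGFb, 155 together, of which 148 changed 2-fold or more. At unadjusted p under 0.05 the count was 1314. With the block it was 322 (66 higher, 256 lower), with array weights 450 and with only the 4 arrays compared 353, and without STAT3-deficient replicate 1 or 2 it was 35 or 28 and without WT replicate 1 or 2 it was 37 or 32. Il21, Rora, Tmem176b, Gm17767, Pdpn, Gpr15 and Tnfsf11 kept their call whichever of these arrays was left out, and the other named genes lost it in at least 3 of the 4 fits, with adjusted p from 0.0329 to 0.365, Il17a among them (0.0839 to 0.232). With the STAT3-deficient TGFb and IL-6 with TGFb replicate 1 arrays exchanged, as a mix-up of these would require, the count was 113 (21 higher, 92 lower). Il17a and Rora then changed by -2.84 and -2.01 and did not pass (adjusted p = 0.133 and 0.134), and of the lists called here Th17, STAT3 targets, follicular helper and glycolysis genes passed as lower (adjusted p up to 0.028). The Th1, cell cycle and naive and migration calls were lost (means 0.58, -0.03 and -0.29, adjusted p = 0.16, 0.99 and 0.08), and the interferon mean turned to -0.18 (adjusted p = 0.25). The survival and aryl hydrocarbon receptor lists passed as lower (adjusted p = 0.028 for both). With both the block and the 5' minus 3' difference of Actb in the fit, the count was 239 (45 higher, 194 lower), 147 of them among the 155, and the follicular helper and naive and migration calls were lost (adjusted p = 0.083 for both).

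**Figure D2:**
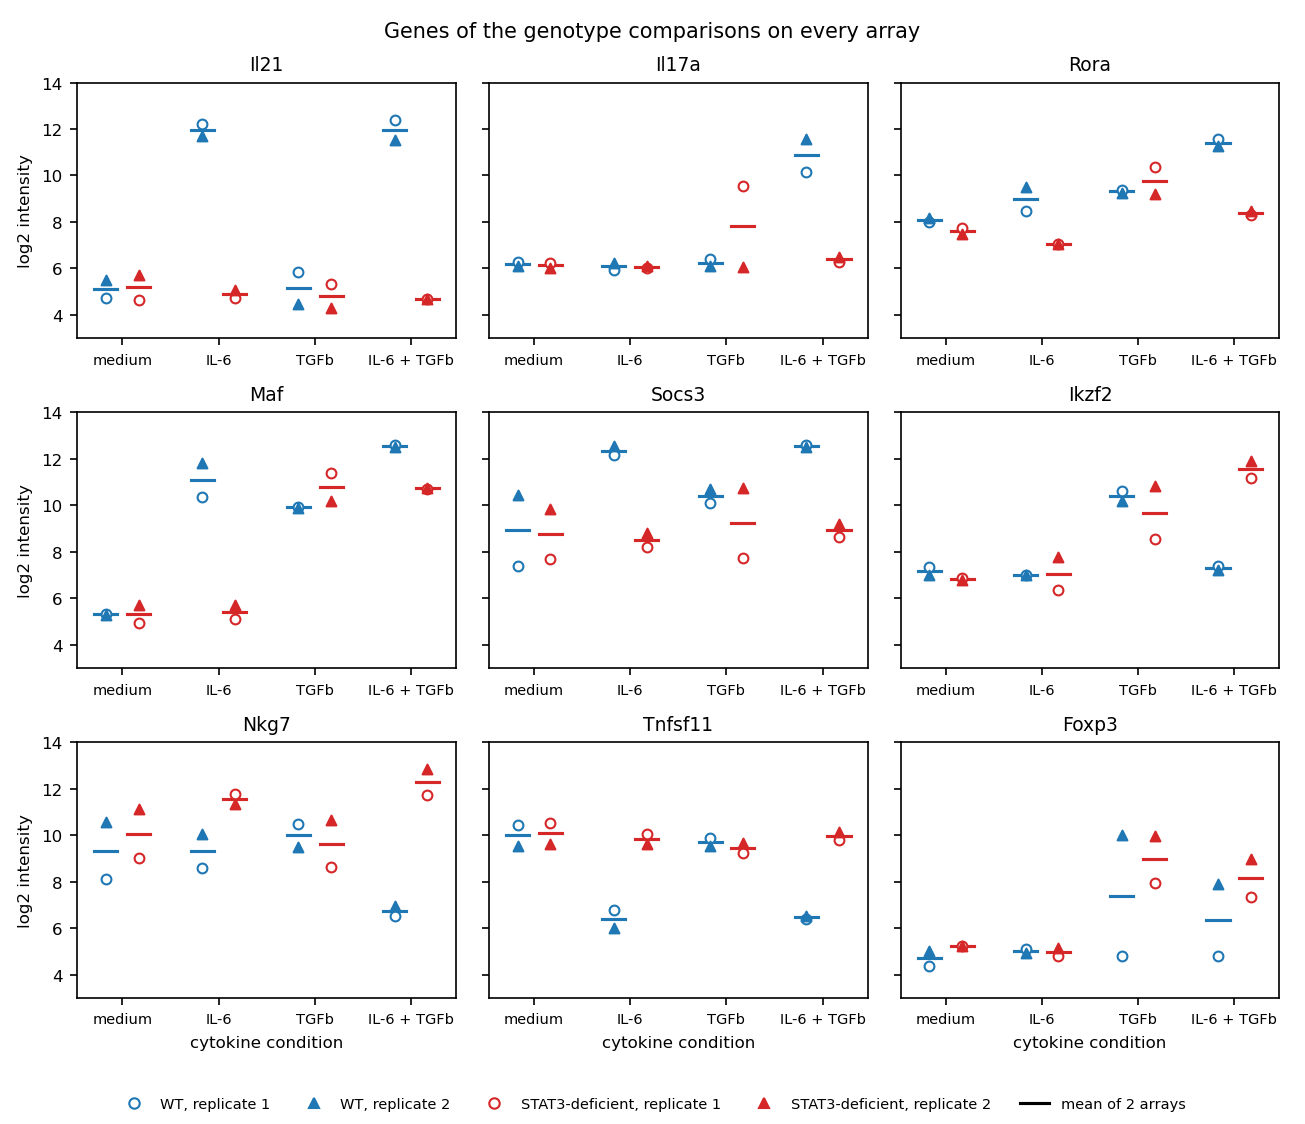
Log2 intensity (y axis) of 9 genes on each of the 16 arrays (points) by genotype and condition (x axis), with bars at the mean of 2 arrays. Under IL-6 with TGFb, the WT mean of Il21 is 11.96 and that of Il17a 10.87, and the STAT3-deficient mean of Nkg7 is 12.28.

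The next comparison asked what STAT3 contributes under IL-6 alone. Il21 was again far lower in STAT3-deficient cells (132-fold, log2 change -7.05, SE 0.53, n = 2 arrays per group, adjusted p = 0.000371). Maf, a transcription factor that drives Il21, fell from 11.08 ± 1.05 to 5.43 ± 0.42 (SD, n = 2), or 50.3-fold (adjusted p = 0.000424). Ahr, the aryl hydrocarbon receptor, and Rora also fell (log2 changes -3.32 and -1.93, adjusted p = 0.0235 and 0.0242), but 3 of the 7 other Rora probe sets had the opposite sign. Il17a read 6.07 and 6.1, close to the level minimum in both genotypes (change -0.04, SE 0.81, adjusted p = 0.985).

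Other large falls were in Myo6, a myosin (log2 change -5.59), the secreted Serpinf1 (-4.98), the small GTPase Gem (-4.91) and Lgals3, the lectin galectin-3 (-4.39). Their adjusted p were 0.0453, 0.00807, 0.0143 and 0.0143. Ecm1 fell by 4.17 (SE 0.41, adjusted p = 0.00124) and Adamtsl4 fell by 3.8 (SE 0.45, adjusted p = 0.00433), while Sema4f and Frmd4b changed by -3.77 and -3.73 (adjusted p = 0.0155 and 0.0439). In STAT3-deficient cells, Il21, Maf, Ahr, Myo6, Gem, Adamtsl4 and Frmd4b lay below log2 6, as did Fasl and Mlf1 in WT cells. Among the genes that rose, Lad1, Dapl1 and Tnfsf11 changed by 3.51, 3.45 and 3.43 (adjusted p = 0.0212, 0.0155 and 0.00352). Fasl, the death ligand, rose by 3.03 and Nr4a3, a nuclear receptor induced by T cell receptor signals, by 2.63 (adjusted p = 0.0275 and 0.0224). Gm9222, Mlf1, the small nucleolar RNA host Snhg3 and the mitochondrial Timm10 and Ndufa5 rose by 3.26, 2.35, 2.06, 2.02 and 1.87, with adjusted p from 0.0112 to 0.0482.

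Of the 16 measured panel genes 4 passed, Il21, Maf, Ahr and Rora. Socs3 read 8.49 ± 0.43 and 12.36 ± 0.26 (SD, n = 2), a change of -3.87 that did not pass (adjusted p = 0.0692) and passed with the block (adjusted p = 0.011). Bcl3 changed by -2.99 (adjusted p = 0.0546, and 0.00133 with the block). Batf, Il10 and Ifng changed by -1.47, -1.98 and 3.38 (adjusted p = 0.117, 0.249 and 0.294). The values of Gata3, Bcl2, Il6ra, Tbx21, Bcl6 and Foxp3 were -1.88, -1.09, -0.74, 0.81, -0.1 and -0.05, with adjusted p of 0.33 or more.

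Of 23 Th17 genes 4 fell and 0 rose, and 6 fell adjusted over the list alone, with a median of -0.74 (adjusted p = 0.00063, and adjusted p = 0.28 with an estimated correlation). Of 28 STAT3 targets and feedback genes 2 fell, Prdm1, which encodes Blimp-1 (log2 change -3.05, below log2 6 without STAT3), and Jak3 (-1.3), and 8 fell adjusted over the list alone. Their median was -1.07 (adjusted p = 1.7e-05, and adjusted p = 0.28 with an estimated correlation), and 9 fell with the block. Of 17 follicular helper genes Il21 and Maf fell, and 4 fell adjusted over the list alone and likewise with the block (median -0.36, adjusted p = 0.046, adjusted p = 0.61 with an estimated correlation and adjusted p = 0.11 with the block). Of 19 Th1 genes Fasl rose and Hlx, a Th1 transcription factor, fell (log2 change -1.46, below log2 6 without STAT3), against 2 higher and 1 lower adjusted over the list alone and 3 higher and 2 lower with the block (median 0.49, adjusted p = 0.23). Of 28 survival genes 2 fell, the apoptosis inhibitors Birc2 (log2 change -1.13) and Cflar (-1.01), with 3 lower adjusted over the list alone and 5 lower with the block. Their median was -0.63 (adjusted p = 0.039, and adjusted p = 0.28 with an estimated correlation). The follicular helper call was lost without STAT3-deficient or WT IL-6 replicate 2 (adjusted p up to 0.38), and the survival call without these or WT IL-6 replicate 1 (up to 0.16).

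Of 31 glycolysis and hypoxia genes 1 fell, the enolase Eno2 (log2 change -1.74, below log2 6 without STAT3), with 2 lower adjusted over the list alone and 5 lower with the block. Their median was -1.03 (adjusted p = 9e-04, and adjusted p = 0.72 with an estimated correlation). The mean of the list differed between genotypes by -1.09 and -1.16 within replicate numbers 1 and 2 under IL-6, by -0.66 and -0.5 under IL-6 with TGFb, by -0.06 and -0.2 in medium, and by -1.99 and 0.06 under TGFb, where replicates of 1 group stood apart. Of 23 genes of naive cells and migration 2 fell, the sphingosine phosphate receptor S1pr4 (log2 change -1) and the integrin Itgb7 (-0.97), with 7 lower adjusted over the list alone and 8 lower with the block. Their median was -0.75 (adjusted p = 0.039, and adjusted p = 0.28 with an estimated correlation). Of 33 early activation genes, Nr4a3 and the phosphatase Dusp4 (log2 change 1.75) rose and Tnfaip3, which encodes A20, fell (-1.91), with 2 higher and 3 lower adjusted over the list alone and 2 higher and 5 lower with the block. The median and mean of this list were -0.04 and -0.1 while the test leaned up (adjusted p = 0.99). The glycolysis call was lost without WT IL-6 replicate 2 (adjusted p = 0.069), and that of naive and migration genes without either WT IL-6 array or STAT3-deficient IL-6 replicate 2 (up to 0.27).

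In all, 73 genes were higher and 355 lower without STAT3 under IL-6, 428 together, of which 346 changed 2-fold or more. At unadjusted p under 0.05 the count was 2826. The share of higher calls was 17.1%, and after a further quantile normalization 36% (104 higher, 185 lower), so the balance of directions depends on the scaling. With the block the count was 1490 (309 higher, 1181 lower), with array weights 23 and with only the 4 arrays compared 22. Without STAT3-deficient IL-6 replicate 1 or 2 it was 27 or 102, and without WT IL-6 replicate 1 it was 213. Without WT IL-6 replicate 2 the balance turned, but differences between replicate numbers enter that unbalanced fit. Il21, Maf, Ecm1, Adamtsl4 and Tnfsf11 kept their call whichever of the 4 arrays was left out, and the other named genes lost it in 1 to 4 of the fits, with adjusted p up to 0.231. A sign of RNA quality moved with genotype on the replicate 2 arrays. The 5' minus 3' differences of Actb and Gapdh were -1.71 and -0.61 on STAT3-deficient IL-6 replicate 2, the lowest of all 16 arrays, and -1 and -0.23 on WT IL-6 replicate 2. With both the block and the Actb difference in the fit the count was 411 (46 higher, 365 lower), of which 233 were among the 428, and the follicular helper, survival and naive and migration calls were lost (adjusted p = 0.24, 0.058 and 0.16).

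Under TGFb, a cytokine that the labels place outside STAT3 activation, and in medium, 0 genes passed limma's test between the genotypes. At unadjusted p under 0.05 the counts were 89 under TGFb and 17 in medium (237 and 37 with the block). Of the same 16 panel genes 0 passed, with changes under TGFb from -2.01 (Tbx21) to 1.57 (Il17a) and a smallest unadjusted p of 0.08, and in medium from -0.76 (Bcl3) to 1.29 (Ifng) and a smallest unadjusted p of 0.25. Under TGFb, 6 of 16 lists passed with 0 members called over all genes and 0 adjusted over the list alone. Lower were 31 glycolysis and hypoxia genes (median -0.89), 42 interferon response genes (-0.71) and 21 sterol genes (-0.58), each with adjusted p = 3.2e-09, 28 STAT3 targets and feedback genes (-0.45, adjusted p = 3.4e-05) and 48 cell cycle genes (-0.22, adjusted p = 4.8e-06). The 17 follicular helper genes were higher (0.2, adjusted p = 0.018), and each of the 6 had adjusted p = 0.54 with an estimated correlation. STAT3-deficient TGFb replicates 1 and 2 correlated less with each other than any other pair of replicates (r = 0.906 across genes, against up to 0.981), and STAT3-deficient replicate 2 correlated with WT TGFb replicate 2 at 0.992. Il17a read 9.55 and 6.07 on STAT3-deficient TGFb replicates 1 and 2, and 6.29 and 6.51 on those of IL-6 with TGFb. Without STAT3-deficient TGFb replicate 2 the count was 38 (26 higher, 12 lower) and Il17a passed with a log2 change of 3.31 (adjusted p = 0.0265). Without STAT3-deficient TGFb replicate 1 the mean of the glycolysis list turned from -0.97 to 0.23 (adjusted p = 0.075), that of the follicular helper list from 0.5 to -0.18 (0.66), and the other 4 calls were lost (adjusted p from 0.14 to 0.9). With the exchange of that array and STAT3-deficient IL-6 with TGFb replicate 1, only the STAT3 targets passed (adjusted p = 0.021), and the interferon and cell cycle means turned to 0.09 and 0 (adjusted p = 0.14 and 0.2). The cell cycle call was also lost without WT TGFb replicate 1 (0.25) and the follicular helper call without WT TGFb replicate 2 (0.17).

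In medium, 5 of 16 lists passed with 0 members called over all genes and 0 adjusted over the list alone. Higher without STAT3 were the interferon response (42 genes, median 0.25, adjusted p = 6.5e-05), Th1 (19 genes, 0.28), cytotoxic (13 genes, 0.33) and Th2 lists (15 genes, 0.24), and the STAT3 targets were lower (28 genes, -0.11). The adjusted p of the last 4 were 0.021, 0.021, 0.049 and 0.021, that of Th2 was 0.062 with the block, those of Th2 and cytotoxic genes were 0.12 and 0.056 with the block and the Actb difference, and each of the 5 had adjusted p = 0.78 with an estimated correlation. Within replicate numbers 1 and 2, the list means differed between genotypes by 0.53 and 0.18 (Th1), 0.58 and 0.13 (interferon), 0.35 and 0.24 (cytotoxic), 0.13 and 0.6 (Th2) and 0.03 and -0.28 (STAT3 targets). A fit without 1 array compares unequal shares of the replicate numbers, so differences between the numbers enter the values that follow. The means of the Th1, interferon and cytotoxic lists turned to -0.11, -0.1 and -0.19 without WT medium replicate 1 (adjusted p = 0.83, 0.41 and 0.87). Without STAT3-deficient medium replicate 2 the Th1 and interferon calls were lost and the cytotoxic mean turned to -0.14 (adjusted p = 0.75, 0.71 and 0.75). The Th2 mean turned to -0.65 and -0.42 without the same arrays, STAT3-deficient replicate 2 first (adjusted p = 0.0073 and 0.39). The mean of the STAT3 targets turned to 0.34 and 0.49 without STAT3-deficient medium replicate 1 or WT medium replicate 2 (adjusted p = 0.53 and 0.047). The Th1 and interferon lists, which were also higher under IL-6 with TGFb, did not pass the interaction of genotype with that condition (median 0.93 and 0.02, adjusted p = 0.056 and 0.26). Both passed it without STAT3-deficient medium replicate 2, WT IL-6 with TGFb replicate 1 or WT medium replicate 1 (lowest adjusted p = 0.00061 and 0.00016), and Th1 also without STAT3-deficient IL-6 with TGFb replicate 1 (0.048). An absence of called genes does not show that the genotypes were alike under TGFb or in medium.

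The genotype comparisons under IL-6 with TGFb and under IL-6 alone share no arrays. Of the 128 and 355 genes lower without STAT3, 48 were shared (3.5 for independent lists). Of the 27 and 73 higher genes 5 were (0.15). The shared genes included Il21, Rora, Ecm1 and Jak3 among the lower and Tnfsf11 and Lad1 among the higher. Across genes, which are not independent replicates, the log2 changes of both comparisons correlated at r = 0.63 (covariance 0.229). With the block, 158 lower and 18 higher genes were shared, against 18 and 1 with array weights and 30 and 10 after a further quantile normalization. The overlap of 48 was 12 or 24 without STAT3-deficient IL-6 replicate 1 or 2, 7 or 6 without STAT3-deficient IL-6 with TGFb replicate 1 or 2, and 9 without either WT IL-6 with TGFb array. Without these 6 arrays the overlap of 5 was 1 or 2. With the exchange of STAT3-deficient replicate 1 arrays, the overlaps were 30 and 3, and with the block and the Actb difference 73 and 7.

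**Figure D3:**
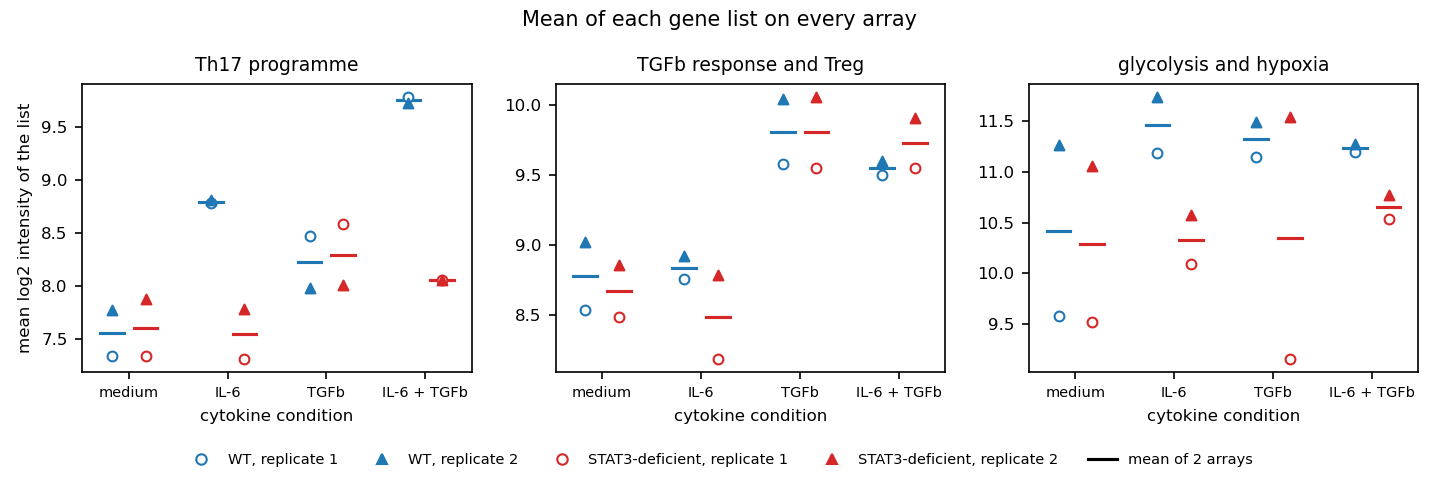
Mean log2 intensity of the measured members of 3 gene lists (y axis; Th17, TGFb response and regulatory T cells, glycolysis and hypoxia) on each of the 16 arrays (points) by genotype and condition (x axis), with bars at the mean of 2 arrays. The median log2 change of the Th17 list without STAT3 under IL-6 with TGFb is -1.56.

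In WT cells, IL-6 with TGFb raised some of the Th17 genes strongly over medium. Maf rose 151-fold (log2 change 7.24, SE 0.47, n = 2 arrays per group, adjusted p = 1.81e-05), Il21 115-fold (6.84, SE 0.53, adjusted p = 6.39e-05) and Ahr 74.2-fold (6.21, SE 0.63, adjusted p = 0.000539). Il17a rose from 6.18 ± 0.13 to 10.87 ± 1.01 (SD, n = 2), or 25.9-fold (adjusted p = 0.0109). Emp1, a membrane protein, Serpinb1a and Klrd1, which encodes the lectin receptor CD94, rose by 7.47, 7 and 6.77 (adjusted p = 0.000656, 0.00361 and 0.00297). Lad1, Dapl1, Fasl, Cd83 and Shtn1 fell, with log2 changes of -4.43, -4.28, -4.22, -3.82 and -3.67 and adjusted p from 0.00256 to 0.0476. In medium, Maf, Il21, Ahr, Emp1, Serpinb1a and Klrd1 lay below log2 6, as did Lad1, Fasl, Cd83 and Shtn1 with both cytokines.

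Of 23 Th17 genes 8 rose and 0 fell, and 11 rose adjusted over the list alone, with a median of 2.14 (adjusted p = 6.2e-13, and adjusted p = 0.011 with an estimated correlation). Of 30 genes of TGFb response and regulatory T cells 6 rose and 1 fell, against 13 and 2 adjusted over the list alone and 10 and 1 with the block. Gpr15 rose by 4.74, Ldlrad4, an inhibitor of TGFb signalling, by 4.08, and Nt5e, the ectoenzyme CD73, by 3.92, while Cd83 fell. Gpr15 and Ldlrad4 lay below log2 6 in medium. The median was 0.96 (adjusted p = 4.5e-05, adjusted p = 0.14 with an estimated correlation and adjusted p = 0.044 with both this and the block). Of 17 follicular helper genes 4 rose, Maf, Il21, Tox2 (log2 change 2.43) and Il6st, the shared IL-6 receptor subunit gp130 (1.76), and Cd200 fell (-2.13), against 7 and 2 adjusted over the list alone and 4 and 2 with the block. Their median was 0.01 and their mean 1 (adjusted p = 0.011, with adjusted p = 0.35 with an estimated correlation and adjusted p = 0.074 with the block and the Actb difference). Of 28 STAT3 targets and feedback genes Il6st and Sbno2 (1.69) rose and Ets2 (-1.3) fell, against 3 and 1 adjusted over the list alone and 4 and 1 with the block (median 0.59, adjusted p = 0.00033, adjusted p = 0.31 with an estimated correlation). Of 33 early activation genes Jun rose (2.78) and the phosphatase Dusp6 fell (-1.52), against 2 and 6 adjusted over the list alone and 1 and 3 with the block (median -0.68, adjusted p = 0.0018, adjusted p = 0.31 with an estimated correlation). The call of the STAT3 targets was lost without WT medium replicate 1 (adjusted p = 0.11), and those of the follicular helper and early activation lists without WT medium replicate 2 (0.15 and 0.092).

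In all, 279 genes rose and 111 fell with IL-6 and TGFb in WT cells, 390 together, of which 360 changed 2-fold or more. With the block the count was 833 (561 higher, 272 lower) and with array weights 979, and without WT IL-6 with TGFb replicate 1 or 2 it was 103 or 112 and without WT medium replicate 1 it was 94. Gpr15, Maf, Il21, Ldlrad4, Ahr, Emp1, Dapl1, Klrd1, Serpinb1a, Lad1 and Fasl kept their call whichever 1 array was left out. The others named here lost it in at least 3 of the 4 fits, with adjusted p up to 0.376, and Il17a kept it in 1 of them (0.0371 to 0.113).

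IL-6 alone raised Il21 and Maf over medium in WT cells. Il21 rose 115-fold (log2 change 6.85, SE 0.53, n = 2 arrays per group, adjusted p = 0.000505) and Maf 54.8-fold (5.78, SE 0.47, adjusted p = 0.000505). In medium Il21, Maf, Gm17767, Moxd1 and Hlx lay below log2 6, so their fold depends on the background. Serpinf1, Gm17767, the monooxygenase-like Moxd1, Ecm1 and Hlx rose by 4.5, 3.41, 3.3, 3.28 and 2.03 (adjusted p from 0.00688 to 0.021). Tnfsf11 fell by 3.59 (SE 0.38, adjusted p = 0.00384), and Dapl1, Lad1, Cnksr3 and Snhg3 changed by -3.85, -3.61, -1.85 and -1.8 (adjusted p from 0.0193 to 0.0448). Of 23 Th17 genes 2 rose, Il21 and Maf, against 4 adjusted over the list alone and 3 with the block (median 0.64, adjusted p = 3.3e-06, adjusted p = 0.11 with an estimated correlation). Of 28 STAT3 targets and feedback genes 0 passed limma's test over all genes, 1 rose adjusted over the list alone and 3 rose with the block (median 1.01, adjusted p = 3.3e-06, adjusted p = 0.28 with an estimated correlation). In all 29 genes rose and 8 fell, 37 together, all 2-fold or more. The count was 218 with the block (157 higher, 61 lower), 24 with the stricter level filter and 12 with array weights. The balance turned without WT IL-6 replicate 2, a fit with unbalanced replicate numbers. Il21 and Maf kept their call whichever 1 array was left out, and the other named genes lost it in 1 to 4 of the fits (adjusted p up to 0.431).

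TGFb alone raised Ctsw, the protease cathepsin W, by 4.63 and Maf by 4.61 over medium in WT cells (log2 changes, SE 0.48 and 0.47, n = 2 arrays per group, adjusted p = 0.00175 for both). Kctd14 rose by 4.08 and Ldlrad4 by 3.93 (adjusted p = 0.000836 for both), and Emp1 by 5.23 (adjusted p = 0.0283). Maf, Ldlrad4 and Emp1 lay below log2 6 in medium and Slc17a6 with TGFb. Skil and Smad7, inhibitors of SMAD signalling that TGFb induces, rose by 2.41 and 1.42 (adjusted p = 0.0436 and 0.046). Slc17a6, the protease inhibitor Cst7 and the caspase Casp4 fell (log2 changes -4.19, -3.84 and -2.83, adjusted p = 0.0283, 0.0355 and 0.0418). Of 30 genes of TGFb response and regulatory T cells 3 rose, against 10 adjusted over the list alone and 7 with the block (median 0.66, adjusted p = 1.9e-08, adjusted p = 0.13 with an estimated correlation and adjusted p = 0.018 with both this and the block). In all 26 genes rose and 3 fell, 29 together, all 2-fold or more, with 62 under the block and 54 with array weights. The count was 16 or 6 without WT TGFb replicate 1 or 2 and 7 or 10 without WT medium replicate 1 or 2. Ctsw, Maf, Kctd14 and Ldlrad4 kept their call in all of these, and the other named genes lost it in at least 3 of the 4 fits, Skil and Smad7 in all 4 (adjusted p up to 0.625).

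Adding IL-6 to TGFb in WT cells raised the cytokines Il21 and Il17a over TGFb alone. Il21 rose 112-fold (log2 change 6.8, SE 0.53, n = 2 arrays per group, adjusted p = 0.00054) and Il17a 24.8-fold (4.63, SE 0.81, adjusted p = 0.0307). Il21 and Serpinb1a lay below log2 6 with TGFb alone, and Lad1 and Scin with both cytokines, so the size of these changes depends on the background. Serpinb1a, Selp, Plac8 and Gpr15 rose by 6.26, 5.43, 4.95 and 3.55 (adjusted p = 0.019, 0.00603, 0.0253 and 0.000555), and Maf and Rora by 2.63 and 2.11 (adjusted p = 0.0348 and 0.0307; 1 of 7 other Rora probe sets was opposite). Lad1, Tnfsf11, Scin, the protease St14 and Litaf fell (log2 changes -4.07, -3.24, -2.55, -2.02 and -1.8, adjusted p from 0.0013 to 0.0233). Of 23 Th17 genes 6 rose and 11 rose adjusted over the list alone (median 0.94, adjusted p = 6e-16, adjusted p = 0.0054 with an estimated correlation). Of 17 follicular helper genes 2 rose and 7 adjusted over the list alone (median 0.86, adjusted p = 5.3e-08, adjusted p = 0.071 with an estimated correlation). In all 59 genes rose and 7 fell, 66 together, all 2-fold or more. The count was 141 with the block (108 higher, 33 lower) and 409 with array weights, and without WT IL-6 with TGFb replicate 1 or 2 it was 14 or 17 and without WT TGFb replicate 1 or 2 it was 13 or 12. Il21, Gpr15 and Litaf kept their call in all of these, and the other named genes lost it in at least 2 of the 4 fits (adjusted p up to 0.313).

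In STAT3-deficient cells, the response to TGFb included genes that TGFb raised in WT cells. Of those named, Maf, Ldlrad4 and Emp1 lay below log2 6 in medium. With TGFb alone, Maf rose by 5.43, Ctsw by 4.89 and Ldlrad4 by 4.67 over medium (SE 0.47, 0.48 and 0.34, n = 2 arrays per group, adjusted p = 0.000483, 0.000983 and 9.44e-05). Emp1 rose by 5.36 and Nt5e by 5.13, and the TGFb receptor Tgfbr1, Skil and Rora by 2.73, 2.44 and 2.15 (adjusted p from 0.0198 to 0.0457; 1 other probe set of Emp1 and 1 of Rora were opposite). Casp4, Gramd1b, the oxysterol receptor Gpr183, Snhg3 and the kinase Map3k8 fell (log2 changes -3.13, -2.37, -2.3, -1.69 and -1.66, adjusted p from 0.0214 to 0.0429). Of 30 genes of TGFb response and regulatory T cells 5 rose, against 12 adjusted over the list alone and 10 with the block (median 0.94, adjusted p = 1.7e-08, adjusted p = 0.13 with an estimated correlation and adjusted p = 0.018 with both this and the block). In all 39 genes rose and 7 fell, 46 together, all 2-fold or more. The count was 196 with the block (145 higher, 51 lower), 97 with the block and the Actb difference (77 higher, 20 lower), 30 with probe sets averaged, 14 with array weights, 247 without STAT3-deficient TGFb replicate 2 (159 higher, 88 lower), and 13 or 9 without STAT3-deficient medium replicate 1 or 2. Maf, Ctsw and Ldlrad4 kept their call in all of these single-array fits, and the other named genes lost it in at least 2 of the 4 (adjusted p up to 0.302).

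With IL-6 and TGFb together, STAT3-deficient cells again raised Maf (log2 change 5.39, SE 0.47, n = 2 arrays per group, adjusted p = 0.000519), Ctsw (4.97, adjusted p = 0.001) and Ldlrad4 (4.19, adjusted p = 0.000454) over medium. Emp1, Ikzf2 and Ahr rose by 5.21, 4.72 and 4.05 (adjusted p = 0.0291, 0.0113 and 0.0337), and the myosin Myh10 fell by 2.46 (adjusted p = 0.0352). Maf, Ldlrad4, Emp1 and Ahr lay below log2 6 in medium. Of 30 genes of TGFb response and regulatory T cells 2 rose, against 12 adjusted over the list alone and 5 with the block (median 0.76, adjusted p = 7.1e-12, adjusted p = 0.051 with an estimated correlation, and adjusted p = 0.0073 with both the block and an estimated correlation). In all 17 genes rose and 1 fell, 18 together, all 2-fold or more, with 38 under the block and 48 with array weights. Without STAT3-deficient IL-6 with TGFb replicate 1 or 2 the count was 7 for either, and without STAT3-deficient medium replicate 1 or 2 it was 8 or 5. With the exchange of STAT3-deficient replicate 1 arrays it was 38 (34 higher, 4 lower). Maf, Ctsw and Ldlrad4 kept their call without any 1 array and the other named genes lost it in every such fit (adjusted p from 0.0857 to 0.408).

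IL-6 gave 0 calls in limma's test in STAT3-deficient cells, alone against medium or added to TGFb. The counts at unadjusted p under 0.05 were 173 and 473 (420 and 875 with the block, with 0 calls in both), and without STAT3-deficient TGFb replicate 2 adding IL-6 gave 10 calls. The 23 Th17 genes had a median of -0.09 when IL-6 was added to TGFb (adjusted p = 0.39, 0 members called over all genes or adjusted over the list alone). The 42 interferon response genes passed the list test with 0 members called over all genes or adjusted over the list alone. Their median was 0.48 with IL-6 against medium (adjusted p = 6.9e-11, and adjusted p = 0.61 with an estimated correlation) and 1.01 when IL-6 was added to TGFb (adjusted p = 7.4e-17, and adjusted p = 0.46 with an estimated correlation). The former call was lost without STAT3-deficient IL-6 replicate 1 (adjusted p = 0.47), and the Th17 list passed as lower without STAT3-deficient TGFb replicate 2 (adjusted p = 0.0088). With the exchange of STAT3-deficient replicate 1 arrays, the interferon mean turned to -0.42 when IL-6 was added to TGFb (adjusted p = 0.00071).

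The genotypes share no arrays, but their responses are not independent, since same-numbered arrays varied together. Medium arrays of both genotypes correlated at 0.992 across genes within each replicate number. Replicates within STAT3-deficient medium and within WT medium correlated at 0.953 and 0.944. The counts for independent lists leave this out, so they do not measure chance here. Of 26 genes raised by TGFb in WT and 39 in STAT3-deficient cells, 19 were shared (0.078 for independent lists), and 47 with the block. This overlap was 8 or 9 without STAT3-deficient medium replicate 1 or 2, 6 without WT TGFb replicate 2 and 6 or 9 without WT medium replicate 1 or 2. Of 279 and 17 genes raised by IL-6 with TGFb, 15 were shared, against 0.36 (27 with the block, 32 with array weights). Without STAT3-deficient IL-6 with TGFb replicate 1 or 2 these were 6 or 5, and without STAT3-deficient medium replicate 1 or 2 they were 7 or 4. Comparisons within a genotype share the medium arrays. Of 26 genes raised by TGFb in WT cells, 21 were among the 279 raised by IL-6 with TGFb (0.56 for independent lists). In 20 simulations against the same medium arrays no gene was changed, so shared calls there test nothing. The log2 changes correlated across genes at 0.7 (simulated 0.5) with a covariance of 0.252 (simulated 0.0727). Of 29 genes raised by IL-6 in WT cells, 12 were among those 279 (0.62 for independent lists). The correlation was 0.64 (simulated 0.51) and the covariance 0.239 (simulated 0.0734). In STAT3-deficient cells, 14 genes were shared by the 17 and 39 raised with IL-6 and TGFb and with TGFb (0.051 for independent lists). The correlation was 0.75 (simulated 0.5) and the covariance 0.179 (simulated 0.0728). With the block these overlaps of 21, 12 and 14 were 48, 88 and 29. That of 21 was 38 with array weights, 10 without either WT IL-6 with TGFb array, 11 or 5 without WT TGFb replicate 1 or 2 and 5 or 9 without WT medium replicate 1 or 2. That of 12 was 19 with probe sets averaged, 6 or 7 without WT IL-6 with TGFb replicate 1 or 2 and 2 without WT medium replicate 1. That of 14 was 7 without STAT3-deficient replicate 1 of IL-6 with TGFb or of medium, and 5 without replicate 2 of either. Without both medium replicate 1 arrays the overlaps of 19, 15, 21, 12 and 14 were 6, 4, 5, 2 and 5, and without both TGFb replicate 1 arrays that of 19 was 31. With the exchange of STAT3-deficient replicate 1 arrays that of 15 was 25, and with the block and the Actb difference those of 19 and 12 were 29 and 19. Part of the excess may come from the shared controls.

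Whether a cytokine response differed between the genotypes was tested as an interaction. For IL-6 with TGFb, 17 genes passed, 3 with a higher and 14 with a lower response without STAT3. Il21 responded less by -7.33 (SE 0.74, adjusted p = 0.00926) and Gpr15 by -3.22 (SE 0.42, adjusted p = 0.0326), while Tnfsf11 responded in the other direction by 3.4 (SE 0.54, adjusted p = 0.0469). Il21 and Gpr15 lay below log2 6 in medium. Of 23 Th17 genes 3 had a lower response, Il21, Tmem176b and Tmem176a, and 7 adjusted over the list alone (median -1.69, adjusted p = 2.2e-14, adjusted p = 0.0076 with an estimated correlation). The 28 STAT3 targets and feedback genes had a median of -0.75 (adjusted p = 1.4e-05, adjusted p = 0.36 with an estimated correlation) with 0 members past limma's test over all genes or adjusted over the list alone. The count of 17 was 27 with the block (4 higher, 23 lower), 9 after a further quantile normalization, 42 with array weights and 11, all lower, with the exchange of STAT3-deficient replicate 1 arrays. It was 0, 0, 1 and 0 without STAT3-deficient IL-6 with TGFb replicates 1 and 2 and medium replicates 1 and 2, and 3, 1, 0 and 2 without the same WT arrays. Il21 lost its call in 4 of the 8 fits that left out 1 array, and every other named gene in all 8 (adjusted p from 0.0541 to 0.301).

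For IL-6, 3 genes passed with a lower response without STAT3, Il21 (log2 -7.11, SE 0.74, adjusted p = 0.0125), Maf (-5.69, adjusted p = 0.0205) and Tha1, a threonine aldolase (-3.04, adjusted p = 0.0341). All 3 lay below log2 6 in STAT3-deficient cells under IL-6. Of 23 Th17 genes 2 had a lower response, and 4 adjusted over the list alone (median -0.61, adjusted p = 0.00015, adjusted p = 0.25 with an estimated correlation). The count of 3 was 17 with the block (1 higher, 16 lower) and 0 with the block and the Actb difference (adjusted p of the 3 up to 0.122). The balance turned without WT IL-6 replicate 2, a fit with unbalanced replicate numbers. The 3 genes lost their call in 4 to 6 of the 8 fits that left out 1 array (adjusted p up to 0.171). For TGFb 0 genes passed limma's test, with 35 at unadjusted p under 0.05 (99 with the block), and 1 gene passed without STAT3-deficient TGFb replicate 2. The counts of 35 and 99 lie below 0.05 of the 13007 genes, so differences could be missed here too. The interferon response (median -1, adjusted p = 6.9e-13), sterol (-0.63, 1.3e-05), glycolysis (-0.66, 0.00026), cell cycle (-0.22, 0.0051) and follicular helper lists (0.34, 0.0051) passed this interaction with 0 members called over all genes or adjusted over the list alone, and each had adjusted p = 0.7 with an estimated correlation. The interferon call stayed in all 8 fits without 1 array and was lost with the exchange of STAT3-deficient replicate 1 arrays (adjusted p = 0.48), as were the other 4 (adjusted p from 0.082 to 0.9). Without STAT3-deficient TGFb replicate 1 the cell cycle, sterol and follicular helper calls were lost (adjusted p = 0.49, 0.97 and 0.97) and the glycolysis mean turned from -0.83 to 0.36 (adjusted p = 0.0078). Without STAT3-deficient medium replicate 2 or WT medium replicate 1 the glycolysis, sterol and follicular helper calls were lost (adjusted p up to 0.92, 0.82 and 0.49), and WT TGFb replicates 1 and 2 left out ended the cell cycle and follicular helper calls (0.73 and 0.074).

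**Figure D4:**
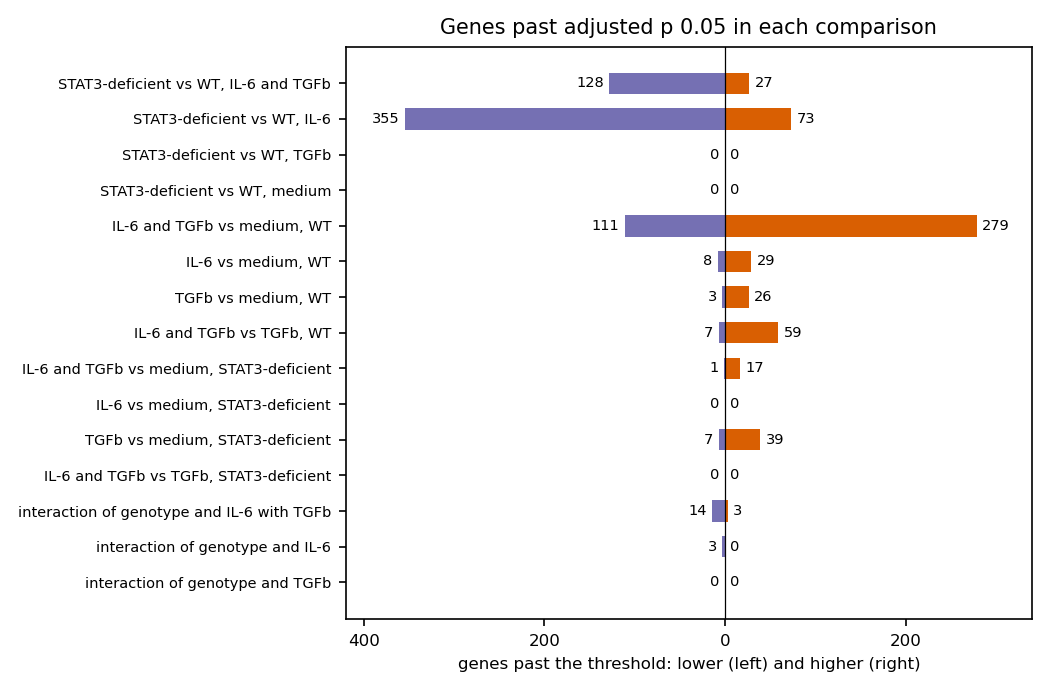
Number of genes past limma's test at a Benjamini-Hochberg adjusted p under 0.05 (x axis), lower to the left and higher to the right of 0, for each of the 15 comparisons. The counts are highest for STAT3-deficient against WT cells under IL-6 (73 higher, 355 lower) and for IL-6 with TGFb against medium in WT cells (279 higher, 111 lower).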

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

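The tests of explanations here were all chosen after the results were seen, as were the counts for probe sets without a single symbol, while the interaction tests were planned.

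The response to IL-6 with TGFb differed between the genotypes for 17 genes by the interaction test, and the response to IL-6 for 3. For IL-6 with TGFb, the response was lower without STAT3 for Il21 (-7.33), Pdpn (-4.4), Gm17767 (-4.28), Fnbp1l (-3.61), Cwh43 (-3.48), Gpr15 (-3.22), Tmem176b (-3.02) and Tmem176a (-2.46). It was higher for Tnfsf11 (3.4), Litaf (1.87) and Adgre5 (1.78), the first of which fell with the cytokines in WT cells. Il21, Pdpn, Gm17767, Cwh43 and Gpr15 lay below log2 6 in medium in both genotypes. The adjusted p of these 11 lay between 0.00926 and 0.0481. For IL-6, the response was lower for Il21 (-7.11), Maf (-5.69) and Tha1 (-3.04). The median interaction of the Th17 genes was -1.69 for IL-6 with TGFb and -0.61 for IL-6. Single arrays moved these counts, to between 0 and 3 for IL-6 with TGFb. With the block and the Actb 5' minus 3' difference in the fit, 0 passed for IL-6. For IL-6 most calls were higher without WT IL-6 replicate 2, a fit with unbalanced replicate numbers.

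Of 4509 probe sets with no or several symbols that passed the level filter, in a fit of their own, 17 passed between the genotypes under IL-6 with TGFb (1 higher, 16 lower) and 15 under IL-6 (2 higher, 13 lower). In WT cells the counts were 24 for IL-6 with TGFb, 6 for IL-6 and 3 for TGFb against medium, and 14 for IL-6 added to TGFb. In STAT3-deficient cells they were 1 for IL-6 with TGFb and 3 for TGFb, and 4 passed the interaction of genotype and IL-6. These transcripts are not named here.

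The replicate 1 and 2 arrays of STAT3-deficient cells under TGFb stood apart from each other (r = 0.906 across genes), and the comparison of genotypes under TGFb moved with them. An exchange of genotype labels between the TGFb replicate 1 arrays is argued against by Stat3, which read lower on the array labelled STAT3-deficient (log2 difference -3.33). An exchange of the STAT3-deficient TGFb and IL-6 with TGFb replicate 1 arrays stays open. The array labelled IL-6 with TGFb correlated better with the other array of that label than the TGFb array did (0.973 against 0.944, difference 0.0299), but it also correlated better with TGFb replicate 2 (0.944 against 0.906, difference -0.0377). Il17a read 9.55 on the array labelled TGFb and 6.29 on that labelled IL-6 with TGFb. With both exchanged, the change of Il17a between the genotypes under IL-6 with TGFb was -2.84 in place of -4.48 and did not pass (adjusted p = 0.133), and the count there was 113 in place of 155. A difference in how these cultures responded to TGFb was not tested.

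The glycolysis and hypoxia list was lower without STAT3 under IL-6 (camera adjusted p = 9e-04, 0.72 with an estimated correlation). The list mean was lower within both replicate numbers, by -1.09 and -1.16, a gap of -0.07. Variation between single cultures stays open. The genotype difference under TGFb was -1.99 in number 1 and 0.06 in number 2, a gap of 2.05, but it came from the group whose replicates stood apart. Under IL-6 with TGFb the values were -0.66 and -0.5, and in medium -0.06 and -0.2, with gaps of 0.16 and -0.14. An effect of STAT3 on these genes was not tested apart from the cultures and stays open too. The rule for this explanation first took the largest gap alone, by which culture variation would account for the pattern, and was changed to count conditions after the gaps were seen.

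Nkg7 and Gzmk, genes of cytotoxic cells, were higher without STAT3 under IL-6 with TGFb. NK cells in those cultures are argued against, since the NK markers had a median change of -0.1 and Tyrobp, abundant in NK cells, read at most 5.17 on the STAT3-deficient arrays, while Klrd1 and Klre1 changed by -3.08 and -2.07. CD8 T cells are argued against, since the larger change of Cd8a and Cd8b1 was 0.2, and the sort for CD4 would remove them. The hypothesis left is that the CD4 cells themselves expressed these genes more when they lacked STAT3. It was reached by setting the others aside and was not itself tested.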

How the results depend on the processing

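The fits and list tests described above as added after seeing the data were not planned, and the other alternatives were.

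With a replicate block, counts of genes were 322 (main 155) between the genotypes under IL-6 with TGFb, 1490 (428) under IL-6, and in WT cells 833 (390) for IL-6 with TGFb, 218 (37) for IL-6, 62 (29) for TGFb and 141 (66) for IL-6 added to TGFb. In STAT3-deficient cells they were 38 (18) for IL-6 with TGFb and 196 (46) for TGFb, and for the interactions 27 (17) and 17 (3). All genes called without the block kept their call with it in every comparison. Of the named genes, the block added calls of Stat3 (-2.72) and of Socs3 and Bcl3 under IL-6 and IL-6 with TGFb, and of the lists described it ended the follicular helper call under IL-6 and the Th2 call in medium and added the aryl hydrocarbon receptor call under IL-6 with TGFb. It changed no other call of these. With array weights, the counts were 450 and 23 between the genotypes under IL-6 with TGFb and under IL-6. In WT cells they were 979, 12, 54 and 409, in STAT3-deficient cells 48 and 14, in the order above, and 42 for the interaction of IL-6 with TGFb. Only the 4 arrays compared gave 353 under IL-6 with TGFb and 22 under IL-6. A stricter level filter gave 24 for IL-6 in WT cells, the mean of probe sets 30 for TGFb in STAT3-deficient cells, and quantile normalization again 9 for the interaction of IL-6 with TGFb. The cause was not tested for any of these.

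Leaving out single arrays gave 28 to 37 genes between genotypes under IL-6 with TGFb, 27 to 547 under IL-6, 0 to 38 under TGFb and 0 in medium. In WT cells it gave 94 to 262 for IL-6 with TGFb, 3 to 370 for IL-6, 6 to 16 for TGFb and 12 to 17 for IL-6 added to TGFb. In STAT3-deficient cells it gave 5 to 8 for IL-6 with TGFb, 0 for IL-6, 9 to 247 for TGFb and 0 to 10 for IL-6 added to TGFb, and for the interactions 0 to 3, 0 to 119 and 0 to 1. Without both medium replicate 1 arrays the counts against medium were 79, 4 and 8 in WT cells (IL-6 with TGFb, IL-6, TGFb), 6 and 9 in STAT3-deficient cells (IL-6 with TGFb, TGFb), and 0 for the interactions of IL-6 with TGFb and of IL-6. Without both TGFb replicate 1 arrays, TGFb in WT cells gave 54. With the exchange, IL-6 with TGFb in STAT3-deficient cells gave 38 and its interaction 11, while IL-6 with TGFb between the genotypes gave 113. With the block and the Actb difference, IL-6 with TGFb between the genotypes gave 239, TGFb in STAT3-deficient cells 97 and the interaction with IL-6 0. Fewer arrays leave a wider spread and unbalanced replicate numbers. Why some arrays raise a count when left out was not tested.

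Stat3 was lower without STAT3 in every setting. Under IL-6 with TGFb the change of -2.72 lay at the threshold and passed it with the replicate block, the stricter filter, the trend and robust prior, the array weights and only the 4 arrays compared (-2.72 in each), with quantile normalization again (-2.69) with the exchange (-2.99) and with the block and the Actb difference (-2.65). It ranged from -3 to -2.44 when single arrays were left out. Under IL-6 the call was lost with array weights (-3.1), and single arrays left out gave -3.44 to -2.76. Under TGFb they gave -3.53 to -1.52. The cause was not tested.

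Of the 237 values of named genes, 166 were called, and 0 changed sign past the threshold in any setting. The mean of probe sets ended 16 calls, no filter 22, the stricter filter 1, the trend and robust prior 2, quantile normalization 27, array weights 44, only the 4 arrays 24 the exchange 24 of 59 and the block with the Actb difference 31. Leaving out single arrays repeated 720 called values and ended 467 of these calls, and turned the sign of 56 uncalled values. Of 50 repeats of the overlaps of gene calls without single arrays 34 moved by over 1.5 times, as did 7 of 7 with the block, 4 with array weights, 2 with quantile normalization again, 1 with the mean of probe sets 3 of 5 with the exchange, 3 of 7 with the block and the Actb difference, 5 of 5 without both medium replicate 1 arrays and 1 of 3 without both TGFb replicate 1 arrays. Of the list tests, 88 of 240 passed in the main setting, 4 with an estimated correlation, 7 with the block and an estimated correlation (without the Th17 list between the genotypes under IL-6 with TGFb, adjusted p = 0.062) and 90 with the block (82 shared with the main setting). After quantile normalization again 226 of 240 stayed on their side of the threshold, and with the block and the Actb difference 219 did, with 18 calls lost. The glycolysis list under TGFb ranged from -2.16 to 0.23 in its mean when single arrays were left out, and turned to 0.23 without STAT3-deficient TGFb replicate 1. The same fits gave -0.18 to 1.17 for the follicular helper and -0.59 to 0 for the cell cycle list, and for the interaction of genotype and TGFb -0.55 to 0.04 for cell cycle, -2.03 to 0.36 for glycolysis and -1.37 to -0.04 for sterol genes. In medium, single arrays left out gave -0.74 to 0.49 for the STAT3 targets, -0.11 to 0.83 for Th1, -0.65 to 1.38 for Th2, -0.1 to 0.81 for interferon and -0.19 to 0.79 for cytotoxic genes. With the exchange, the interferon mean turned to -0.18 and 0.09 between the genotypes under IL-6 with TGFb and under TGFb, to -0.42 when IL-6 was added to TGFb in STAT3-deficient cells and to -0.53 for the interaction with IL-6 and TGFb. For TGFb, the cell cycle mean became 0 between the genotypes and 0.04 for the interaction, and the glycolysis mean -0.15 for the interaction. The cause was not tested for these. On these arrays the level minimum limits what a low signal shows, and 2 arrays per group limit the calls.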

Other observations

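The choice of genes described here beyond the rule for named genes was made after the results were seen.

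Further single genes changed in WT cells under IL-6 with TGFb against medium. Sgk1, a kinase of salt sensing that acts in Th17 cells, rose from log2 6.79 ± 0.99 to 12.62 ± 0.07 (SD, n = 2), or 56.9-fold (limma adjusted p = 0.0135). Cyp1b1, an enzyme induced by the aryl hydrocarbon receptor, rose by 2.2, and S1pr1 and Foxo1, genes of naive and migrating T cells, rose by 2.86 and 1.35 (adjusted p = 0.0238, 0.0401 and 0.0327). P4ha1, a prolyl hydroxylase of the hypoxia list, rose by 2.08, and Klrc1, which encodes the partner of CD94, by 3.84 (adjusted p = 0.0278 and 0.0095). Cyp1b1 and Klrc1 lay below log2 6 in medium. Ifih1, an RNA sensor of the interferon response, and the cell cycle kinase Cdk1 changed by -3.28 and -1.08 (adjusted p = 0.012 and 0.0329). Each of these 8 lost its call in at least 2 of the 4 fits that left out 1 array, with adjusted p up to 0.3.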
